A study of Trichoderma reesei QM6a with 6 samples.

How the data were processed

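RNA was sequenced from 6 samples, 3 of Trichoderma reesei QM6a and 3 of its ace1 deletion. The libraries were stranded TruSeq libraries made from poly(A)-enriched RNA, per the labels' protocols. FastQC 0.11.5, kallisto 0.43.1 and DESeq2 1.14.1 were used, per the submitters' processing notes. The transcript set and the genome build are not given in the sources used here. The deposited table of each sample gives an estimated count, a TPM value and a length per transcript, per the file headers. The TPM values deposited by the authors depend on effective length and have the same sum in each sample, so they hold no depth. The lengths are coding lengths, since 99.1% are multiples of 3. The deposited table of the whole series holds a normalized signal per gene, which is a count divided by 1 factor per sample. Multiplying by that factor gave whole reads (within 0.05) for 92.5% to 96.1% of the values.

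The sample tables name transcripts and the series table names genes by locus tag, and no deposited table pairs these names. They were joined here by their counts in all 6 samples. All 9113 genes found a partner among 9115 transcripts, and 99.2% of the values were equal after rounding. Of these genes 8526 had a single partner, and 587 shared their 6 counts with another gene, with at most 11 counts in total. Symbols came from a reference table of assembly v2.0 that held 9109 of the genes and a symbol for 234. It gives no products, and its start coordinates were used only to break the gene order for the test of neighbouring genes. Genes without a symbol are printed by locus tag, and the name after "listed as" comes from the gene list fixed beforehand. Of the 33 listed identifiers with a reference symbol, 33 had the symbol listed, with tef1a accepted for tef1 and man5a for man1.

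Groups, tests, alternatives, the rule for named genes and 10 gene lists by identifier were fixed before the data were examined. A further 12 lists by symbol were written after the reference table was seen and before any test. The 22 lists planned by product words were not run, and 15 listed identifiers that needed a product were left out. The named genes are ace1, the 10 largest increases and decreases among called genes with a mean TPM of at least 5 and no overlap between strains, the 8 largest of each among genes with a symbol (in place of an informative product), the regulators, up to 4 members of each other list, and the controls. Genes named beyond that rule were chosen after their values were seen. The value of 1 listed regulator is not reported here.

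Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, robust estimation) in R 4.3.3. Calls needed a two-sided Benjamini-Hochberg adjusted p below 0.05. Standard errors are the log2 change divided by the root of the F statistic, and none is given where a group had no count. CPM values are scaled by TMM. The common biological coefficient of variation was 8.63%. Folds against a group without counts use a floor of 3 counts per library, and ratios with 1 to 3 counts have a 95% counting interval. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), and again with an estimated correlation and with fry. The first tests a list against the other genes, whereas fry tests whether its genes move one way on balance. With the preset correlation 4 of 13 lists passed, with an estimated correlation 0 of 13, and with fry 13 of 13. The variant with an estimated correlation takes its degrees of freedom from the libraries and not from the genes, so it has less power. It was not tried on simulated lists, and failing it does not show that correlated members explain a list. Neighbouring genes were taken from the order in the reference table. A drop in the start coordinate was taken as a break, and pairs and runs across a break were not counted.

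The alternatives were DESeq2 1.42.0, other scalings (RLE, upper quartile, library totals), other count filters, limma on log2(TPM + 1), log2(TPM + 0.1) and log2(normalized count + 1), a fit without robust estimation, a replicate block, and leaving out each library. Recovered reads, calls shared by 5 scalings, and list tests with no low count filter were added after seeing the data. The procedures were tested on simulated data for 7769 genes, of which 200 were changed. There edgeR recovered 94.2% of 2-fold and 99.1% of 4-fold changes with 14 false calls, and DESeq2 91.9% and 97.4% with 14. A simulated raised list gave a camera p of 8.48e-59 and an unchanged one 0.744. The simulated changes went in both directions at equal library composition, so these rates do not cover errors of scaling in the real libraries. The simulated genes were drawn independently, so correlation within a list was not simulated either. Replicates of a strain differed by more than sampling noise, with a chi-square per degree of freedom of 2.96 to 28.5, so none was treated as a second deposit of another library. This does not show that they came from separate cultures.

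The rules for both explanations of the spread among QM6a libraries were altered after their values were known. For the correlation across genes a bootstrap interval (1000 draws) was added, since the value lay within sampling error of its bound of 0.1. For the share of variable genes, the share by sign of the fold was set beside the planned share of calls. By the rules as first written, the correlation would have counted against its explanation and the share for its own.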

Results

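Trichoderma reesei is a filamentous fungus known for the cellulases and hemicellulases it secretes, and Ace1 is a zinc finger protein known as a repressor of their genes. Transcripts of the strain QM6a and of an ace1 deletion made in it (Δace1) were measured by poly(A) RNA sequencing, with 3 libraries of each strain. Both strains grew for 24 h on 1% D-glucose in shake flasks at 28 °C and 250 rpm. The washed mycelium then spent 3 h on 1% D-mannitol, a sugar alcohol. The libraries held 5482552 to 6424125 estimated counts in Δace1 and 6072118 to 6938203 in QM6a. The floor of 3 counts corresponded to 0.432 to 0.547 CPM of a library's total, and it covers counting error only. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples. The only comparison of the series asks which transcripts differ between Δace1 and QM6a after the transfer.

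The deleted gene was measured first. The ace1 transcript (TRIREDRAFT_75418) had 6, 7 and 14 counts in the Δace1 libraries and 8432, 7765 and 8001 in the QM6a libraries. This was 1.32 ± 0.749 CPM (counts scaled to a common library size by TMM) against 1499.6 ± 17.4 (SD, n = 3 each), a log2 change of -10.17 with a standard error of 0.16. Each library therefore carried the ace1 level of its label.

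The transcripts of acu3 and acu9, which encode the enzymes of the glyoxylate bypass, were far higher in Δace1. Isocitrate lyase (acu3) rose from 10.7 ± 0.751 to 2469.9 ± 84.9 CPM and malate synthase (acu9) from 17.9 ± 2.66 to 2817 ± 180 CPM (SD, n = 3 each). All 7 tested of 13 listed hemicellulases and all 6 tested of 7 beta-glucosidases rose. All 42 ribosomal protein genes fell, with a median log2 change of -2.88. These lists passed camera, a test of a list against other genes, and did not pass it with an estimated correlation (adjusted p = 0.174 for each). For beta-glucosidases the estimated correlation was -0.128, below the preset 0.01, so correlated members do not account for the loss of that list. With an estimated correlation camera also has fewer degrees of freedom and so less power. How much of the loss comes from this was not tested. In edgeR's quasi-likelihood test 6274 of 7769 genes changed at a Benjamini-Hochberg adjusted p below 0.05, 3202 higher and 3072 lower in Δace1, and 3139 of them changed at least 2-fold (1803 higher, 1336 lower).

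The direction of small changes, and the count of genes at least 2-fold lower, depended on how the libraries were scaled. The 100 most abundant genes took 28.1% to 29.5% of the counts in Δace1 and 33.3% to 36.3% in QM6a. The 10 most abundant went the other way, with 11.5% to 13.2% in Δace1 and 7.65% to 9.80% in QM6a. Relative to the TMM scaling used here, the median of all genes moved by 0.16 (log2) with upper-quartile scaling, by 0.50 with library totals and by 0.75 on log2(TPM + 1). The share of calls that were higher was 51.0% with TMM, 71.8% with library totals and 80.5% on log2(TPM + 1). Across 5 scalings 4450 genes were called in the same direction, 3135 higher and 1315 lower. Under all 5 scalings 1740 genes were at least 2-fold higher and 581 at least 2-fold lower. The first principal component of the log2 CPM values separated the strains and held 95.6% of the variance.

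**Figure D1:**
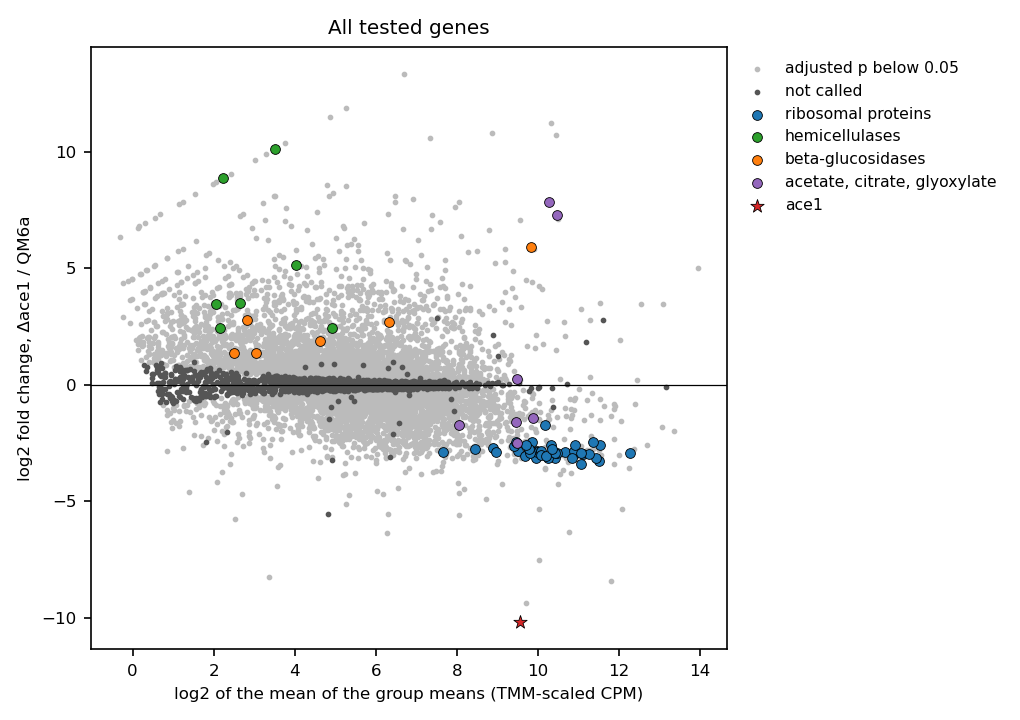
Log2 fold change of Δace1 over QM6a (vertical axis) against the log2 of the mean abundance in TMM-scaled CPM (horizontal axis) for the 7769 tested genes, with 3 libraries per strain. Grey points passed an adjusted p of 0.05 in edgeR, dark points did not; the 42 ribosomal protein genes lie between -3.38 and -1.71 and ace1 at -10.17, and genes without a count in QM6a are drawn at a fitted value that is no measured fold.

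Tested hemicellulases were low in QM6a and higher in Δace1. Of 13 listed members 7 were tested and all 7 rose at least 2-fold, with a median log2 change of 3.51, which was also 3.51 with the genes at 0 in QM6a set to their bound (camera, adjusted p = 0.00271; adjusted p = 0.174 with an estimated correlation). TRIREDRAFT_72704 (listed as agl2, an alpha-galactosidase) rose from 0.867 ± 0.102 to 31.6 ± 0.719 CPM, a log2 change of 5.16 with a standard error of 0.20. TRIREDRAFT_72526 (glr1, an alpha-glucuronidase) and TRIREDRAFT_121127 (bxl1, a beta-xylosidase) had no count in QM6a. They were at least 40.6-fold and at least 16.8-fold higher in Δace1, against a floor of 3 counts per library. TRIREDRAFT_111849 (xyn4) rose by 3.51 and TRIREDRAFT_123283 (abf1) by 3.46 on the log2 scale. The xylanase genes TRIREDRAFT_74223 (xyn1) and TRIREDRAFT_123818 (xyn2) were among 6 untested members, none above 4 counts in a library, so a difference in them was not detectable at this depth. Members near the floor in QM6a enter the test only if they have counts in Δace1, which favours a rise among those tested. With no low count filter, 7 of the 13 rose and 6 were not called (camera, adjusted p = 0.00756; adjusted p = 0.169 with an estimated correlation).

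Beta-glucosidases, which cleave cellobiose and other beta-glucosides, rose in all 6 tested members, with a median log2 change of 2.30 (camera, adjusted p = 0.0127; adjusted p = 0.174 with an estimated correlation). The gene cel3b rose from 29.5 ± 4.59 to 1792 ± 165 CPM (SD, n = 3 each), a log2 change of 5.92 with a standard error of 0.12. TRIREDRAFT_76227 (listed as cel3e) rose by 2.70, cel1a by 2.78 and cel3c by 1.90 on the log2 scale. The untested cel3a had 16, 6 and 6 counts in Δace1 and 1, 0 and 0 in QM6a. With library totals in place of TMM the adjusted p of this list was 0.0734.

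Most of the listed cellulase genes stayed near the floor in both strains. Of 13 listed cellulases and cellulose-active proteins 9 were untested, with at most 8 counts in a library, and cel12a, cel61b and cip2 had none. The cellobiohydrolase gene cel7a had 8, 4 and 1 counts in Δace1 and 4, 3 and 2 in QM6a. Of the 4 tested members, TRIREDRAFT_123992 (listed as swo1, swollenin) rose by 2.62 and TRIREDRAFT_72567 (cel6a) by 2.38 on the log2 scale, the latter from 0.616 ± 0.386 to 3.29 ± 0.537 CPM. Being near the floor in QM6a, TRIREDRAFT_72567 entered the test through its Δace1 counts, which favours a rise. TRIREDRAFT_49081 (cel74a) fell by 0.74 and cel5b fell by 0.24 with TMM, whereas cel5b rose with library totals and on log2(TPM + 1) and was not called with upper-quartile scaling (-0.077). On log2(TPM + 1) TRIREDRAFT_49081 had a log2 change of 0.018 that did not pass the test, and with library totals it was not called either.

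All 3 genes listed for sugar uptake and xylose and arabinose catabolism, TRIREDRAFT_3405, xyl1 and xdh1, rose, and the list was too small to be tested as one. TRIREDRAFT_3405 (listed as crt1, a sugar transporter) rose from 1.13 ± 0.536 to 86.6 ± 9.41 CPM, a log2 change of 6.26 with a standard error of 0.19. The aldose reductase gene xyl1 rose by 2.55, the L-arabinitol dehydrogenase gene lad1 by 3.45 and the xylitol dehydrogenase gene xdh1 by 1.52 on the log2 scale. In the list of 8 pentose, galactose and glycerol enzymes 6 rose and 1 fell, and 6 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.201; adjusted p = 0.520 with an estimated correlation). The gene lower in both counts, gld1, fell from 50.1 ± 4.44 to 12.9 ± 0.288 CPM. In each other list the counts adjusted over the list alone were those over all tested genes.

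**Figure D2:**
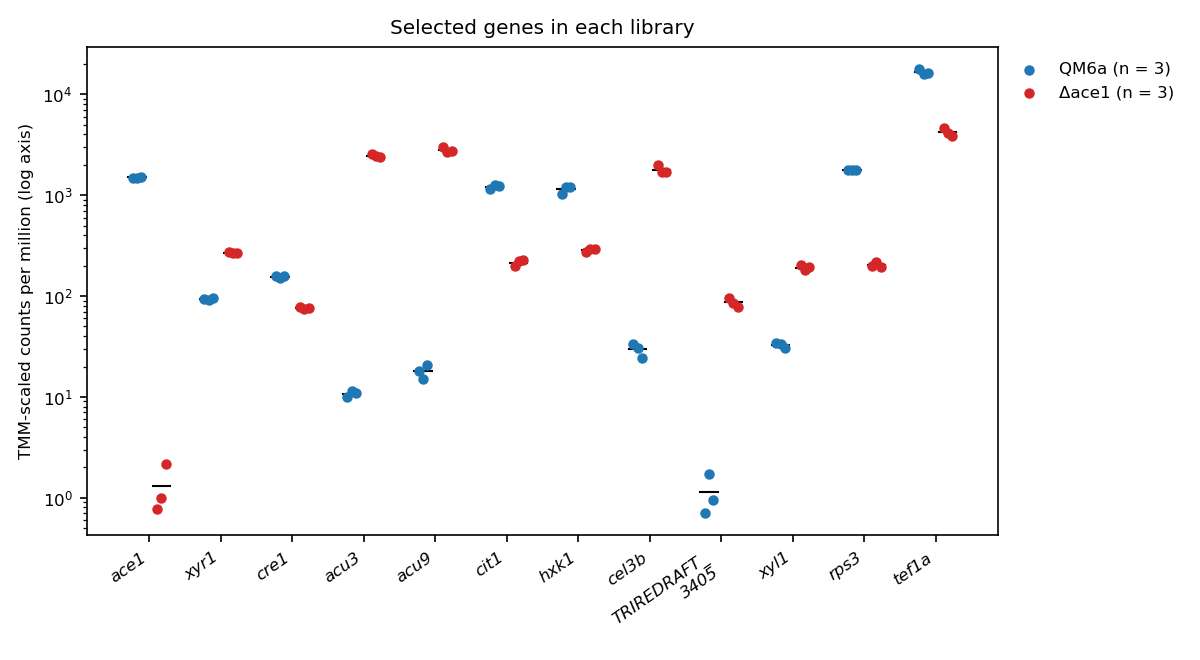
TMM-scaled CPM (vertical log axis) of 12 genes in each of the 3 QM6a libraries (blue) and the 3 Δace1 libraries (red), with the group mean as a black line. The groups do not overlap in any of the genes; acu3 has means of 10.7 and 2469.9 CPM and ace1 of 1499.6 and 1.32 CPM in QM6a and Δace1.

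Regulators of these enzymes changed in both directions. The activator gene xyr1 rose from 93.0 ± 2.64 to 269 ± 4.74 CPM (SD, n = 3 each), a log2 change of 1.53 with a standard error of 0.06 (edgeR, adjusted p = 7.58e-13). The gene of the carbon catabolite repressor, cre1, fell from 156 ± 4.36 to 76.0 ± 1.57 CPM, a log2 change of -1.04. It was called lower under each of the 5 scalings, but the fall was smaller with library totals (-0.54) and on log2(TPM + 1) (-0.26). TRIREDRAFT_120698 (listed as pac1) rose by 1.93, TRIREDRAFT_122284 (vel1) by 1.27 and TRIREDRAFT_77513 (ace3) by 0.61 on the log2 scale. TRIREDRAFT_41617 (lae1) fell by 1.28 and hap2 fell by 0.80 with TMM, and neither was called on log2(TPM + 1). The gene hap5 rose by 0.21, a call lost with DESeq2 (0.19) and without QM6a replicate 3 or Δace1 replicate 1 (0.17 in each). The gene hap3 had a log2 change of -0.08 that did not pass the test. It was above 0 and not called with upper-quartile scaling, and was called higher with library totals and on log2(TPM + 1). Of the 11 listed regulators, ace1 included, 6 rose and 4 fell (camera, adjusted p = 0.686; adjusted p = 0.693 with an estimated correlation).

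Ribosomal protein transcripts took 9.003 ± 0.0608% of the counts in QM6a and 1.76 ± 0.111% in Δace1 (SD, n = 3 each). All 42 genes fell under each of the 5 scalings, with a median log2 change of -2.88 with TMM and -2.11 on log2(TPM + 1) (camera, adjusted p = 4.59e-15; adjusted p = 0.174 with an estimated correlation). The gene rps3 fell from 1782 ± 6.49 to 203 ± 12.1 CPM and rpl35 from 3935 ± 525 to 378 ± 25.3 CPM. The smallest fall was that of rps30, -1.71 on the log2 scale. The gene cpc2, whose product binds the ribosome, fell by 3.20, and the elongation factor gene tef1a fell by 1.98 on the log2 scale.

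Central carbon metabolism changed unevenly. Of 7 acetate, citrate and glyoxylate enzymes 3 rose and 4 fell. Isocitrate lyase (acu3) and malate synthase (acu9) rose by 7.85 and 7.29, and acetyl-CoA synthetase (acs1) by 0.25 on the log2 scale. The citrate synthase gene cit1 fell by 2.50, the isocitrate dehydrogenase gene idh2 by 1.72, and the ATP citrate lyase genes acl1 and acl2 fell by 1.44 and 1.59. The list's median was -1.44 and its mean 1.16, camera placed it lower and fry higher, so it has no common direction (camera, adjusted p = 0.659; adjusted p = 0.684 with an estimated correlation). Among 7 genes of glycolysis and the pentose phosphate pathway 1 rose and 5 fell, with a median of -0.67 that was 0.10 on log2(TPM + 1) (camera, adjusted p = 0.0609, and 0.0394 with no low count filter; adjusted p = 0.520 with an estimated correlation). Hexokinase (hxk1) fell by 1.99 and enolase (eno1) fell by 1.499 on the log2 scale. Glycogen phosphorylase (gph1) rose by 1.66, while ugp1 and gys1 fell by 0.38 and 0.24 with TMM and rose on log2(TPM + 1). With library totals gys1 rose (with upper-quartile scaling it was -0.082 and not called), and ugp1 had a log2 change of 0.12 that did not pass the test.

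The list of chitinases was taken by symbol and includes nag1 and nag2. Of its 19 members 13 were tested, and 11 rose and 0 fell, with a median log2 change of 1.35 (camera, adjusted p = 0.00764; adjusted p = 0.174 with an estimated correlation). The 6 untested members had at most 1 count in a library. With no low count filter 11 of 16 rose and 5 were not called (camera, adjusted p = 0.0193; adjusted p = 0.199 with an estimated correlation). The filter favours a rise among members near the floor in QM6a, such as chi18-rel1 at 0.877 CPM. The largest increases were those of chi18-rel1, 3.88, and chi18-13, 3.02, on the log2 scale. The genes nag2 and chi18-3 did not pass the test, with log2 changes of 0.27 and -0.05, and nag2 ranged from 8.28 to 45.2 CPM among the QM6a libraries. With library totals the adjusted p of the list was 0.0530.

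None of the remaining lists passed camera, and those with fewer than 5 tested members were not tested as lists. All 5 histone genes fell with TMM, with a median of -0.64 that was 0.13 on log2(TPM + 1) (camera, adjusted p = 0.0609, and 0.0335 without Δace1 replicate 1 and 0.0394 with no low count filter; adjusted p = 0.520 with an estimated correlation). Of 6 proteasome subunits 4 rose, with psa5 highest at 0.41 (camera, adjusted p = 0.303). Of 23 G proteins and kinases 6 rose and 10 fell, and their median of -0.02 was above 0 with upper-quartile scaling, library totals and TPM (camera, adjusted p = 0.390). Of 12 secretory pathway genes 4 rose and 5 fell, with a median of -0.05 that changed sign in the same way (camera, adjusted p = 0.686). Of 6 small GTPases and actin regulators 2 rose and 3 fell, with a median of -0.20 that was above 0 with library totals and TPM (camera, adjusted p = 0.512). Of 4 light response genes 3 rose, among them the photoreceptor gene env1 by 2.03 on the log2 scale. Of the folding genes of the secretory pathway, TRIREDRAFT_46902 (listed as hac1) rose by 0.43 and bip1 fell by 0.18 with TMM, the latter higher with library totals and TPM. The call of bip1 was lost with upper-quartile scaling (-0.027), with at least 50 counts in 3 samples (-0.13) and without QM6a replicate 2 (-0.16) or Δace1 replicate 2 (-0.17). Both sorbicillinoid genes that were kept, TRIREDRAFT_73618 and TRIREDRAFT_73621, rose, by 0.91 and 1.67, and the other planned cluster members were left out. Their levels were low, from 3.19 ± 0.939 to 5.93 ± 0.862 CPM and from 0.860 ± 0.594 to 2.79 ± 1.05 CPM. With a mean TPM below 1, neither gene entered the fit on log2(TPM + 1). The hydrophobin gene hfb3 rose by 0.45 and hfb2 fell by 0.60 with TMM. The change of hfb2 was above 0 on log2(TPM + 1), at 0.15, and not called there, with library totals or without QM6a replicate 3 (-0.58).

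The control genes were not level. With TMM tef1a fell by 1.98 and gpd1 by 1.05 on the log2 scale. TRIREDRAFT_44504 (listed as act1, actin) fell by 0.20, was higher with library totals and TPM, and was not called with upper-quartile scaling (-0.039). The gene sar1 fell by 0.15, was higher with library totals and TPM, and was not called with upper-quartile scaling (0.013). With at least 50 counts in 3 samples neither was called (-0.14 and -0.091). Without single libraries both calls could be lost, that of TRIREDRAFT_44504 without QM6a replicate 2 (-0.18) or 3 (-0.19) or Δace1 replicate 3 (-0.15), and that of sar1 without QM6a replicate 2 (-0.14) or 3 (-0.12) or Δace1 replicate 2 (-0.12) or 3 (-0.15). The conidial pigment gene TRIREDRAFT_82208 (pks4), taken as a marker of conidia, had 7, 8 and 12 counts in Δace1 and 4, 8 and 5 in QM6a and was not tested.

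**Figure D3:**
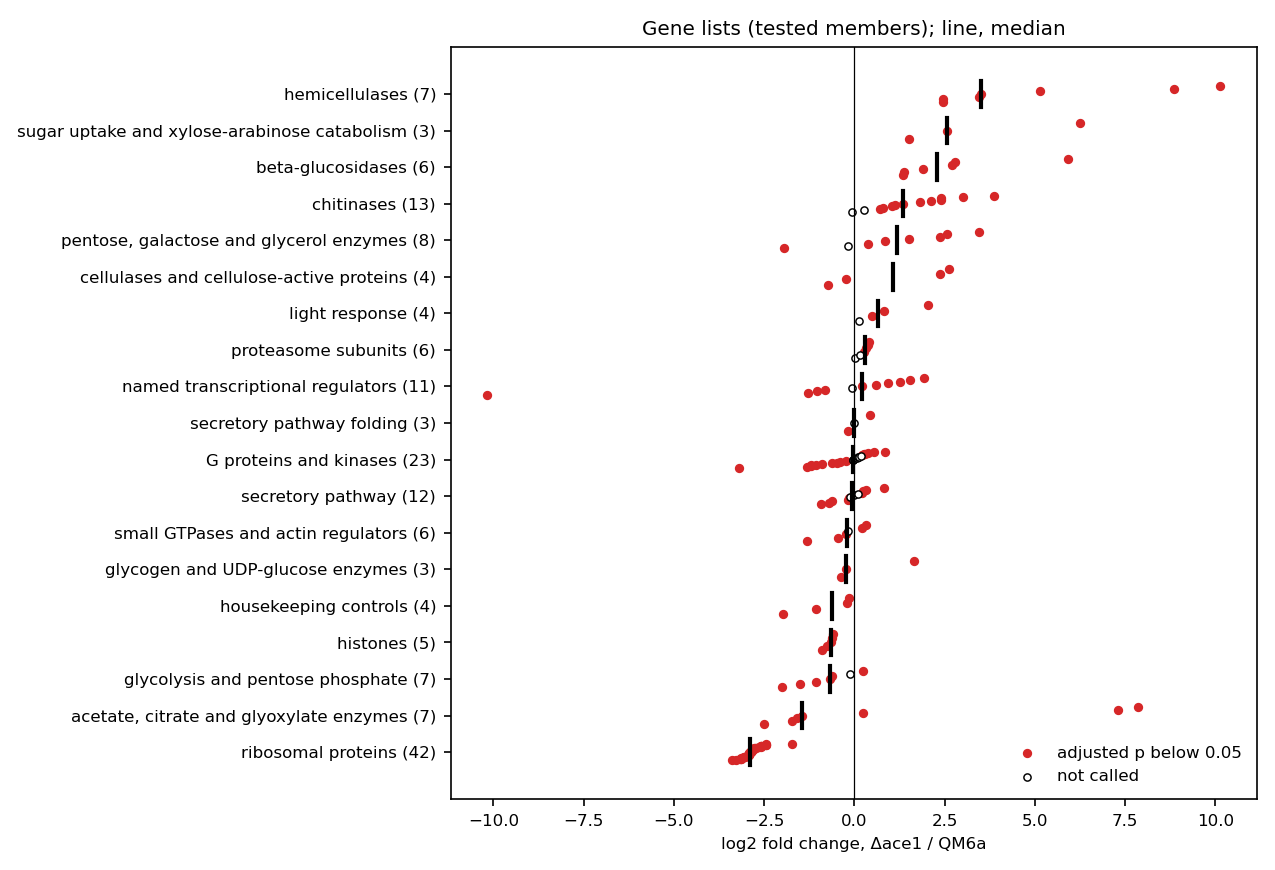
Log2 fold change of Δace1 over QM6a with TMM scaling (horizontal axis) for the tested members of the gene lists with at least 3 of them, whose number stands in brackets, with 3 libraries per strain; red points passed an adjusted p of 0.05 in edgeR, open points did not, and black lines are list medians. The medians run from -2.88 for ribosomal proteins to 3.51 for hemicellulases; those of glycolysis, histones, housekeeping controls, glycogen, small GTPases, the secretory pathway and G proteins change sign on log2(TPM + 1), that of the folding genes with RLE scaling, and hemicellulases without a count in QM6a are drawn at a fitted value.

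Several genes with no symbol were among those with the largest changes. TRIREDRAFT_104277 rose from 1.05 ± 0.254 to 2563 ± 355 CPM and TRIREDRAFT_123241 from 1.62 ± 0.253 to 2768 ± 234 CPM (SD, n = 3 each). TRIREDRAFT_123978 had no count in QM6a and was at least 371-fold higher in Δace1, TRIREDRAFT_68466 at least 139-fold and TRIREDRAFT_62872 at least 105-fold, the last with no call without Δace1 replicate 1. TRIREDRAFT_59843 had 3 counts in all of QM6a and a ratio of 1729 (95% counting interval 591 to 8384). TRIREDRAFT_50618 fell from 1665 ± 68.8 to 2.51 ± 0.731 CPM, TRIREDRAFT_68812 from 7114 ± 825 to 20.8 ± 3.87 CPM and TRIREDRAFT_76633 from 2076 ± 77.9 to 11.4 ± 0.209 CPM.

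Changed genes lay next to each other more often than shuffled calls did. Of 6915 pairs of neighbouring tested genes, 811 had both members changed at least 2-fold in the same direction. The mean over 10000 shufflings was 577 and the highest 654 (one-sided permutation p = 0.0001, the smallest these shufflings can give). The longest run was of 9 genes, TRIREDRAFT_112520 to TRIREDRAFT_124260, all higher in Δace1, with a median log2 change of 2.10. A run of 6 genes that begins with acl1 and acl2 was lower, with a median of -1.47.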

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

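The 6 rounded counts of 1 transcript in the sample tables matched no gene of the series table, and it entered no test. It stood out because it lies outside the tested data and its values in Δace1 all lay above those of the control strain. Its mean was 11.7 ± 1.501 TMM-scaled CPM in Δace1 and 7.23 ± 1.00 in QM6a (SD, n = 3 each). The lowest Δace1 library, 10.03, lay above the highest QM6a library, 8.18, and no explanation was tested.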

How the results depend on the processing

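Of the alternatives, recovered reads, calls shared by 5 scalings (4450 genes) and list tests with no low count filter were chosen after seeing the data. The count of changed genes, 6274, ranged from 5709 (at least 50 counts in 3 samples) to 6786 (log2(TPM + 1)) over the other settings and from 6039 to 6265 with a library left out; DESeq2 called 6069 and recovered reads 6274. The log2 change of ace1 stayed between -10.69 and -8.07. Of the log2 changes of 107 named genes over these settings, 1828 had the same call (hap3 and pdi1 also changed sign while not called), 36 fell short of the threshold, 9 newly passed it and 46 changed sign with a call on at least one side. No pairing by replicate number was detected: the correlations of same-numbered samples were -0.011, 0.032 and -0.047, and the replicate block called 6223 genes. Values near 0 do not exclude shared handling of same-numbered samples.

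The directional counts depended on scaling. Library totals gave 1850 genes lower and 814 at least 2-fold lower. With log2(TPM + 1) 5460 genes were higher and 1326 lower, and 3135 and 589 at least 2-fold. With log2(TPM + 0.1) these were 5443, 1320, 3362 and 617.

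Of all genes called with TMM, 265 were called in the opposite direction with library totals, 816 on log2(TPM + 1), 812 on log2(TPM + 0.1) and 0 with upper-quartile scaling. Among named genes, the log2 changes that turned above 0 with library totals, called or not, were cel5b 0.27, ugp1 0.12, gys1 0.26, TRIREDRAFT_44504 0.30, sar1 0.35, hap3 0.42, bip1 0.31, rho1 0.056 and rac1 0.26, and with upper-quartile scaling sar1 0.013 and hap3 0.080. On log2(TPM + 1), then log2(TPM + 0.1), they were TRIREDRAFT_49081 0.018 and 0.019, cel5b 0.53 and 0.54, ugp1 0.39 and 0.39, gys1 0.53 and 0.53, pgd1 0.10 and 0.10, hh4.2 0.0060 and 0.0060, hh2b 0.15 and 0.15, hh3 0.19 and 0.19, hh4.1 0.13 and 0.13, TRIREDRAFT_44504 0.57 and 0.57, sar1 0.63 and 0.63, hfb2 0.15 and 0.15, hap3 0.69 and 0.69, ire1 0.16 and 0.16, pmt1 0.072 and 0.073, bip1 0.58 and 0.59, rho1 0.33 and 0.33, and rac1 0.53 and 0.53.

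With an estimated correlation the adjusted p of camera was 0.174 for ribosomal proteins, hemicellulases, beta-glucosidases and chitinases, and with library totals 0.0734 for beta-glucosidases and 0.0530 for chitinases. The estimated correlations were 0.236 for ribosomal proteins, 0.092 for hemicellulases, -0.128 for beta-glucosidases and 0.041 for chitinases. With fry the adjusted p was 8.05e-06 for acetate, citrate and glyoxylate enzymes, where the direction turned, 1.65e-05 for G proteins and kinases, 4.13e-05 for glycolysis and for pentose, galactose and glycerol enzymes, 0.000741 for histones, 0.000644 for regulators, 0.00379 for proteasome subunits and the secretory pathway, and 8.095e-06 for small GTPases. Unlike camera, fry does not compare a list with other genes, and all 13 lists tested passed it. With 6274 of 7769 genes called, a pass with fry does not set a list apart from the others. With no low count filter camera gave 0.0394 for both glycolysis and histones and changed no other list's call. Histones had an adjusted p of 0.0453 with the replicate block, and of 0.0335 to 0.0735 with a library left out; the block changed no other list's call, and among named genes only that of sar1. Neighbouring pairs numbered 2046 within 3 positions (mean of shufflings 1699), 2646 without the 2-fold criterion (2256) and 810 with the block. Depth limits the cellulases and hemicellulases left untested. Where not stated, the cause was not tested.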

Other observations

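The tests of library scaling, of swapped labels, of the spread among QM6a libraries and of the gene next to ace1 were chosen after the result was seen, and those of coding length, splits and neighbours before. Several single genes with a symbol outside the lists also differed between the strains. The inositol phosphate synthase gene ino1 fell from 2107 ± 47.4 to 289 ± 8.60 CPM (SD, n = 3 each), a log2 change of -2.87 with a standard error of 0.07. The glutamate synthase gene glt1 fell by 2.72, the arginine pathway gene arg2 by 2.47 and the asparagine synthase gene asn1 by 1.92 on the log2 scale. The ATP synthase genes atp1 and atp2 fell by 1.33 and 1.56. The superoxide dismutase gene sod1 rose from 610 ± 74.0 to 2616 ± 41.6 CPM, a log2 change of 2.10, and the polyubiquitin gene ubi4 rose by 1.75. The genes creb and crec, whose Aspergillus counterparts act in carbon catabolite repression, rose by 1.39 and 1.06. These genes were chosen after their values were seen.

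The fall of ribosomal protein transcripts covers 42 genes. Differences in library composition were predicted to place their median near 0 under some scaling, and the highest median over 5 scalings was -2.11 (log2). The fall was thus larger than the shifts between these scalings. Those shifts moved the median of all genes by at most 0.75, too little to bring this list near 0. The test therefore cannot decide on library composition. A loss of short transcripts would lower other short genes too, but 631 other genes of matched coding length had a median of -0.0044. Swapped libraries are excluded by ace1, at most 2.18 CPM in a Δace1 library and at least 1486 in a QM6a library. The deletion, which the design names, stays open and untested as the reason, and so does a difference between the cultures of the strains, since the labels name no batch or flask.

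The QM6a libraries differed among themselves in a set of genes: 41 of 5681 genes over 15 CPM had an SD above 0.5 (log2), against 7 of 6131 in Δace1, and 35 of the 41 were higher in QM6a 3 than in QM6a 1. The gene nag2 is one of them, with 8.28, 23.1 and 45.2 CPM, and lxr1, below that abundance, had 12, 32 and 95 counts in QM6a 1, 2 and 3. If the QM6a cultures had gone different distances along the change between strains, the difference QM6a 3 minus 1 would correlate across genes with Δace1 minus QM6a 2, yet Pearson's r was 0.0941 (bootstrap interval 0.0495 to 0.138; Spearman's rho 0.0587; 5954 genes, which are not independent replicates), below the bound of 0.1 by less than its error. The 41 genes were called higher in Δace1 less often than all tested genes, by -16.8 percentage points, but their spread keeps them from being called, and by the sign of the fold alone they exceeded all genes by 2.27 points. The interval of r also lies wholly below the r predicted for different distances along the change between strains. Over the 5954 genes it thus argues against that account, with the limit that genes are not independent. The share decides nothing, and what sets these libraries apart stays open.

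The gene next to ace1 in the reference order, TRIREDRAFT_104425, had 2, 0 and 2 counts in Δace1 and 75, 57 and 53 in QM6a, a log2 change of -5.77. Only 8 tested genes, 0.103%, fell as strongly, itself and ace1 included. A candidate explanation is that it was removed or disrupted with ace1. The next gene on that side, TRIREDRAFT_56876, had a log2 change of 0.11 that did not pass the test, and the 4 nearest genes on the other side had at most 1 count in any library. Regulation by Ace1 was not tested and stays open.

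Library Δace1 3 stood apart in 4 genes, chosen after their values were seen. TRIREDRAFT_61593, TRIREDRAFT_104156, TRIREDRAFT_61995 and TRIREDRAFT_48266 were 19.9, 16.5, 9.73 and 16.2 times the mean of the other Δace1 libraries, and 0 of 7769 genes were over 4-fold lower. The highest, TRIREDRAFT_61593, took 1.73% of the counts of that library and 0.0521% and 0.125% of those of Δace1 1 and 2.

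The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split called 6274 genes, and 3139 at least 2-fold, and the highest of the other splits called 0 in both cases, so that 1 of the 10 splits reached the real value. The 811 neighbouring pairs changed in the same direction exceeded every one of 10000 shufflings (highest 654, one-sided permutation p = 0.0001, the smallest they can give), which counts against calls placed at random.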
